A study of Homo sapiens with 4 samples.

How the data were processed

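Total RNA of MCF-7 cells was purified on columns with DNase digestion and converted to labelled cRNA, per the labels' protocols. Cy5 carried the sample with the precursor vector and Cy3 the empty-vector sample on all 4 arrays, per the labels, and no array had the dyes swapped, so a dye bias of a probe stays in its ratio against the empty vector and cancels between the alleles. The arrays were scanned and read out with Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited scanner outputs give spot intensity values (mean and local background signals per channel), which are not yet normalized between dyes, and a log10 ratio of Cy5 over Cy3 computed by that software, per the file headers. Mean signals are printed there to 3 significant digits, so they were rebuilt from the net signal and the array's offset, with a gap to the printed values of at most 0.499%. The series' deposited table of values holds log10 ratios of Cy5 over Cy3 for 33580 spots, whose direction and scale were found by comparison with the scanner log ratios. Between 84.2% and 84.7% of its values were equal within 0.005 plus 0.5% to those of the best matching scanner output, and each column's median was 0; how the authors filtered and centred it is not given in the sources used here. All arrays lay on 1 slide and were scanned in 1 session, per the file headers, so no slide or scan batch could be tested.

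Signals were background-corrected with limma's normexp (offset 50) and normalized within each array by loess (span 0.3), with 0 weight for control spots and for spots marked as non-uniform or population outliers, which were then left out. Saturated spots were kept. Spots of a probe were averaged. A probe was kept if at least 0.5 of its spots were well above background on all arrays of at least 1 group, in Cy5 of C, Cy5 of T or Cy3 of all 4 arrays, which left 28254 of 41000 probes. For each gene name the brightest probe was tested, 21038 in all. Of the probes, 23958 were named through an unversioned RefSeq accession in a table of RefSeq genes (assembly GRCh38.p14, used for names only), 2755 by a current and 1025 by an older symbol, and 13262 kept the name in the file; 34 of 43 names turned into dates by a spreadsheet were restored. Coordinates are those of the files (hg18).

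Models were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with files read by version 1.17.8 of data.table. Group means of C and T over the 4 arrays were tested against 0 and against each other, with Benjamini-Hochberg adjustment over genes, separately for each comparison, and a threshold of 0.05. A further fit of a single mean to the 4 arrays compared either allele with the empty vector, and was added after the data had been seen. All adjusted p values of genes come from limma. The empty-vector samples enter only as the Cy3 channel. Gene lists were fixed before the data were examined (24 lists, at least 5 measured genes) and tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Named genes are, per comparison, the 12 largest rises and 12 largest falls past the threshold with the same sign in all arrays of the comparison (for C against T in both same-numbered differences). Where fewer than 6 passed in a direction, genes in order of unadjusted p made up 6, said not to pass. HOXB8, HOXC8, HOXA7, HMGA2 and ANXA1 where measured, and 2 to 4 members of each described list with the smallest p, were also named.

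Where a probe was not well above background, or was saturated, on every array of a group, an "at least" fold compares normalized log2 signals per channel after loess and Aquantile, with the dim side at the higher of its own signal and the lowest signal well above background; such bounds are open to dye bias. Effects of the C and T vectors were correlated across genes beside 100 simulated pairs of unchanged groups with shared controls. The steps were tested on simulated data with 200 changed genes among 21038 and spreads drawn from the fitted prior. For either allele against the empty vector 90.0% of 2-fold and 99.0% of 4-fold changes were recovered, for C 69.0% and 94.0%, for T 59.0% and 93.0%, and for C against T 2.00% and 74.0%. Spreads were drawn there without regard to the size of a change, and arrays varied independently, so these shares may be too high for the data.

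Alternatives were no background correction, another normexp offset, the scanner software's log ratios, the value table, median centring, Aquantile, filters on dim probes, every probe tested, each array left out, a replicate block, separate channels, eBayes with trend and with robust, a looser threshold, a fold rule, and only the group's own arrays. After the data had been seen, exchanged labels of the arrays C2 and T1, leaving both out, Cy5 signals alone and averaging by empty-vector number were added. A test of seed matches in 3' untranslated regions had been planned if a transcript reference were at hand; none was used here, and matches were searched in the probe sequences only.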

Results

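Gene expression was measured in MCF-7 cells, an established human breast cancer cell line with luminal features and an active estrogen receptor. Cells had been transfected with an empty vector or with a vector expressing the precursor of the microRNA miR-196a-2, in a version with a C allele or a version with a T allele. The question put by the labels was what each version does to gene expression relative to the empty vector, and whether the versions differ. RNA of the precursor-expressing cells was labelled with Cy5 and RNA of the empty-vector cells with Cy3, and each pair was hybridised to a 2-colour Agilent whole-genome array. There were 2 arrays labelled C (C1 and C2) and 2 arrays labelled T (T1 and T2), described by the submitters as biological replicates. Ratios are given as log2(Cy5/Cy3), so a value above 0 is a higher level with the precursor vector. Between 28481 and 30642 of the 43376 probe spots on an array were well above background in Cy5, and between 28901 and 29783 in Cy3. The small number of arrays limits the precision of every value. The arrays carried 0 probes assigned to the microRNA's own gene, so its level was not measured.

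The labels of 2 arrays were in conflict. Over 33580 spots, the deposited value table's column for C1 had a Pearson correlation of 0.965 with the scanner output labelled C1, and that for T2 of 0.957 with the output labelled T2. The column for C2 had a correlation of only 0.547 with the scanner output labelled C2, against 0.959 with the one labelled T1. The column for T1 likewise had 0.545 with its own output and 0.963 with the one labelled C2. Groups below follow the labels of the scanner outputs, and values with the labels of C2 and T1 exchanged stand beside many of the results that differ. If the scanner outputs carry the exchanged labels, each group holds an array of each allele. A difference of C from T then compares the empty-vector numbers in the labels rather than the alleles. The mean over all 4 arrays is the same under either labelling and is described first, as a comparison of either allele with the empty vector that was added after the data had been seen.

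**Figure D1:**
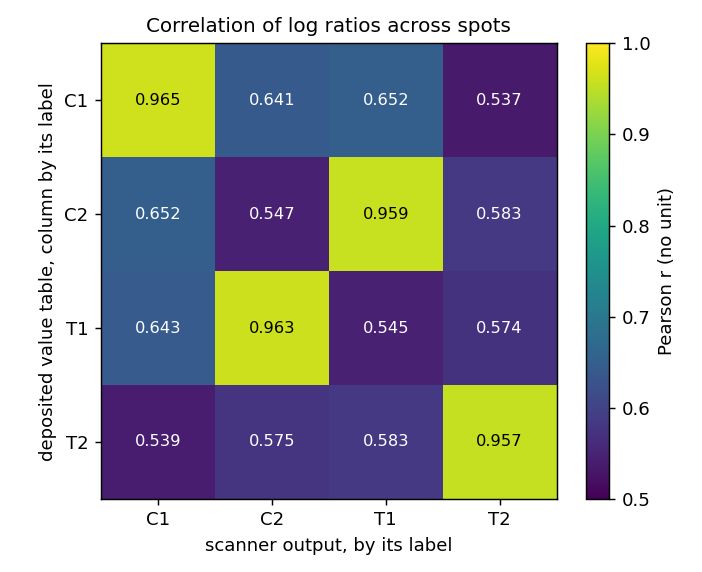
Pearson correlation, across spots, of the log ratios in each column of the deposited value table (vertical axis, by label) with those of each scanner output (horizontal axis, by label). C1 and T2 match themselves at 0.965 and 0.957, whereas the C2 column matches the T1 output at 0.959 and the T1 column the C2 output at 0.963.

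With either allele, the secreted trefoil peptide gene TFF1, an estrogen-responsive gene of breast cells, was 4.96-fold higher than with the empty vector. Its Cy5 signal was saturated on C2, T1 and T2, so this fitted mean may be too low. Its mean log2 ratio was 2.31 ± 0.17 (SD, n = 4; adjusted p = 0.00384), from a probe at chromosome 21, 42655482 to 42655541 of hg18. Several interferon-stimulated genes also rose, with ratios that varied between arrays. IFI27 had a mean log2 ratio of 3.27 ± 1.01 (n = 4; adjusted p = 0.0153), IFI44 3.01 ± 1.90, IFI6 2.38 ± 0.87, IFI44L 2.34 ± 1.22 and MX1, an antiviral GTPase gene, 1.92 ± 1.02. IFI6 stood apart on T2 (1.07, against 2.75 to 2.91 on the other arrays), and a second probe for it had the opposite sign. The Cy3 signal of IFI44L was well above background on only 1 of 4 arrays. The doublecortin-like kinase gene DCLK1 rose by 2.19 ± 0.69, VTCN1 by 1.94 ± 0.70, the phosphatase gene DUSP13A by 1.83 ± 0.31. BMP5, which encodes a bone morphogenetic protein, rose by 1.76 ± 1.05 with Cy3 well above background on 2 of 4 arrays, and BNIP3, a mitophagy gene induced by hypoxia, by 2.21, with ratios from 0.64 on T2 to 4.14 on C1. The keratin gene KRT23 was not well above background with the empty vector and was at least 4.33-fold higher with the precursor (adjusted p = 0.0342), with 3 of its 4 Cy5 signals well above background. Its log2 ratio was 0.37 on T2, against 3.18 to 3.90 on the other arrays.

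The actin-severing protein gene SCIN (chromosome 7, 12658868 to 12658927, hg18) fell by 1.89 on the log2 scale, with an SD of 0.15 over the 4 arrays (adjusted p = 0.00467), which is 3.70-fold. Mean log2 ratios were also below 0 for VAT1L (-2.55 ± 0.43, n = 4; adjusted p = 0.0104), for SELENOP, the gene of a selenium transport protein (-2.44 ± 0.61), for PLEKHS1 (-2.05 ± 0.49, with -1.33 on T2), for CXCL12, which encodes a chemokine (-1.78 ± 0.46), for the metalloprotease gene ADAMTS19 (-1.73 ± 0.45), for the potassium channel gene KCNJ8 (-1.72 ± 0.40), for the transcription factor gene HOXB2 (-1.67 ± 0.43), for BCAT1, an enzyme of branched-chain amino acid metabolism (-1.63 ± 0.26), and for MUCL1 (-1.53 ± 0.60), each past adjusted p 0.05. Cy5 was well above background on 3 of 4 arrays for VAT1L and on 1 of 4 for BCAT1. The cancer-testis antigen genes SPANXA1 (-2.17 ± 0.70) and SPANXD (-1.85 ± 0.57) also fell, but belong to a family of near-identical copies that their probes may not separate.

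**Figure D2:**
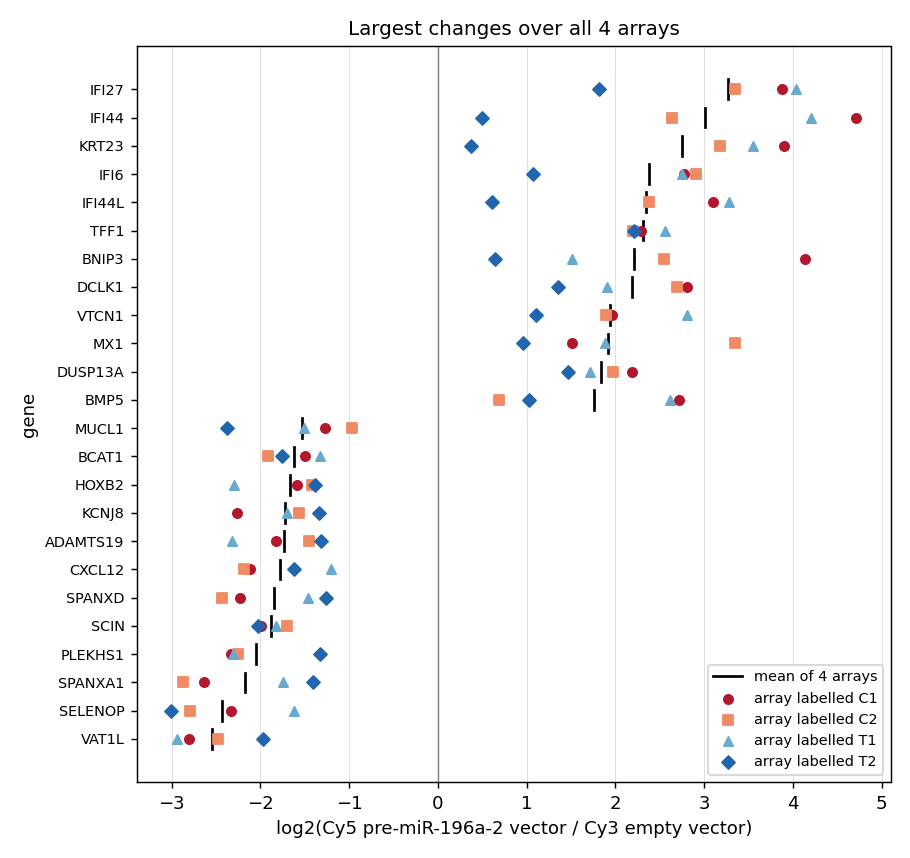
Log2(Cy5/Cy3) (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall over all arrays among named genes past adjusted p 0.05 with 1 sign on all arrays. Each symbol is 1 array and the bar is the mean of the 4. SCIN lies between -2.03 and -1.70, whereas IFI44 lies between 0.50 and 4.71.

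In all, 4874 of 21038 genes passed an adjusted p of 0.05 in the limma test of the 4 arrays against 0, 2292 of them higher and 2582 lower. Of these, 4873 had the same sign on all 4 arrays, which a small p in this test nearly fixes in advance. With no dye swap, probes with a dye bias can enter this count without an effect of the vector. The test took the 4 arrays as independent, although the labels repeat each empty-vector number across arrays. If arrays shared an empty-vector sample, these p values may be too small. The same limit holds for the p values and SDs of single genes over the 4 arrays. With median centring in place of loess, which moved the median of all genes by 0.12 on the log2 scale, 8113 genes passed and 72.0% of them were higher, against 47.0%. The count fell when any array was left out, and most without an array labelled C. Without C1 or without C2 0 genes passed, against 1129 without T1 and 2654 without T2. It was also 0 without both C2 and T1, or with arrays averaged by empty-vector number. The array labelled T2 had the smallest spread of log2 ratios (SD 0.287, against 0.374 to 0.401).

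Genes of the type I interferon response had the largest shift among the 24 gene lists with either allele. Of 34 measured members 15 rose and 0 fell (24 and 0 when adjusted over the list alone), the median log2 ratio was 1.02, and limma's camera gave an adjusted p of 6.72e-09. ISG20 (1.43 ± 0.36, n = 4; adjusted p = 0.0136) and OAS1, a sensor of double-stranded RNA (1.65 ± 0.58; adjusted p = 0.0170), were among them. Genes of the unfolded protein and amino acid stress response had a median of 0.29, with 10 of 33 risen and 0 fallen (11 and 0 adjusted over the list alone; camera adjusted p = 0.000204), among them the endoplasmic reticulum genes PDIA4 (0.73 ± 0.13) and SDF2L1 (0.62 ± 0.10). Hypoxia response genes had a median of 0.50, with 7 of 31 risen and 0 fallen (8 and 0 adjusted over the list alone; camera adjusted p = 0.00136), such as P4HA2 (1.51 ± 0.81) and ENO2 (0.96 ± 0.50). The arrays labelled T added little to this median, with list medians of 0.07 on T1 and 0.04 on T2 against 1.25 on C1 and 0.67 on C2. Heat shock genes had a median of 0.10, with 4 of 22 risen and 0 fallen (3 and 0 adjusted over the list alone; camera adjusted p = 0.0141), including the chaperone genes HSPB1 (1.03 ± 0.13) and HSPA8 (0.67 ± 0.24). Among p53 target genes 2 of 28 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.27; camera adjusted p = 0.0144), and both, AEN (0.56 ± 0.18) and BBC3 (0.69 ± 0.32), act in apoptosis. That share risen was smaller than the 2292 of 21038 over all genes tested. Among apoptosis regulators 6 of 31 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.16; camera adjusted p = 0.0164), BCL2L11 (0.76 ± 0.39) and BCL2A1 (0.38 ± 0.09) among them, of which the latter protects cells from death. With an estimated correlation between genes the adjusted p was 0.778 for the interferon, hypoxia, heat shock and p53 lists and 0.701 for the stress response and apoptosis lists, so these camera calls hold only with the preset correlation. The heat shock call ended without C1 (adjusted p = 0.0719), the apoptosis call with no filter on dim probes (0.0544), and the p53 call without C2 (0.2003) and without both C2 and T1 (0.612).

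Genes of the G2/M phase and mitosis were lower with either allele, with 12 of 52 fallen and 0 risen (22 and 0 adjusted over the list alone), a median of -0.48 and a camera adjusted p of 6.72e-09. TOP2A, the topoisomerase of dividing cells, had a mean log2 ratio of -0.86 ± 0.36 (n = 4; adjusted p = 0.0213), and CENPF, a kinetochore gene, -0.91 ± 0.52. For the G1/S and S phase list 3 of 49 genes fell and 0 rose (0 and 0 adjusted over the list alone), the median was -0.19 and the camera adjusted p 0.0154. The 3 were the replication genes CDT1 (-0.63 ± 0.36), RFC3 (-0.53 ± 0.30) and PRIM1 (-0.53 ± 0.34). Over all genes tested 2582 of 21038 fell, a larger share than in the G1/S list. Its call ended without C1 (adjusted p = 0.0848), C2 (0.2003), T1 (0.0860) or both C2 and T1 (0.811), its median on T2 was 0.20, and its median turned to 0.10 with median centring. With an estimated correlation the adjusted p was 0.778 for the G2/M list and 0.785 for the G1/S list. Cytosolic ribosomal protein genes had a median of 0.35, with 37 of 76 risen and 1 fallen (46 and 3 adjusted over the list alone; camera adjusted p = 1.14e-10, and 0.701 with an estimated correlation), and randomly drawn genes of like brightness had a mean median of 0.43. Other lists, such as the stress response and heat shock lists, were not compared with genes of like brightness.

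**Figure D3:**
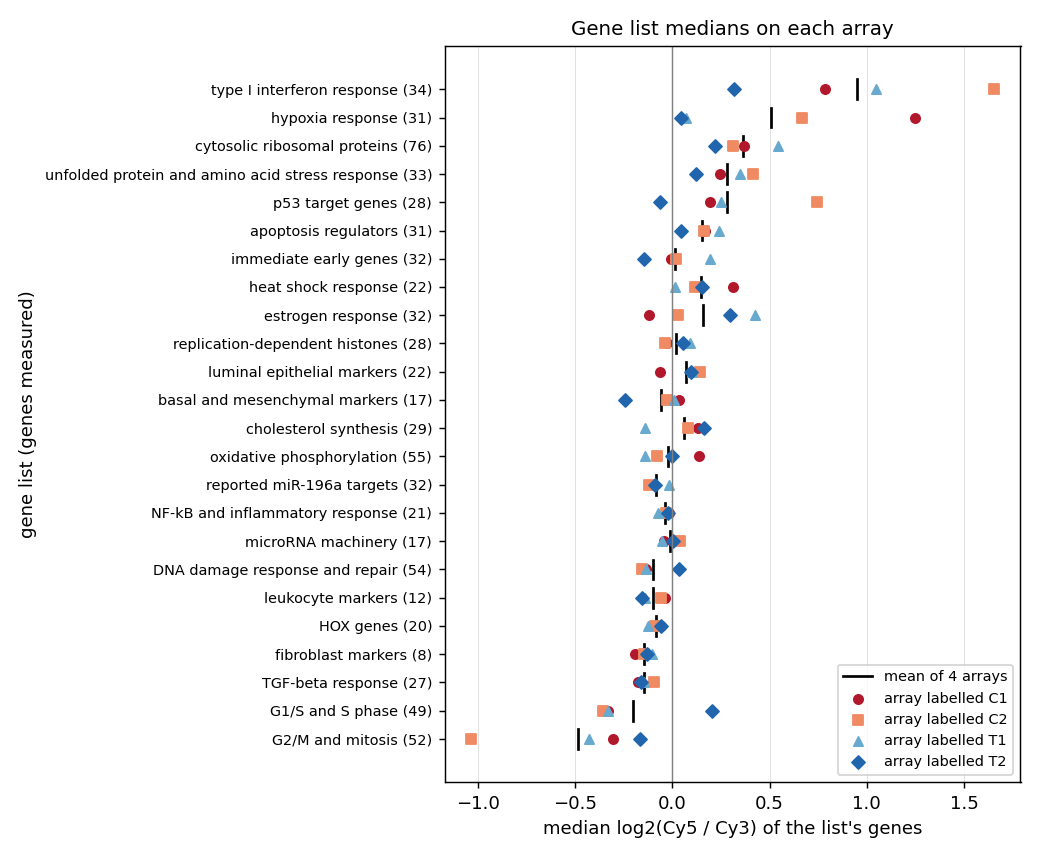
Median log2(Cy5/Cy3) (horizontal axis) of each of the 24 gene lists on each array, with the number of measured genes after the list's name; symbols are arrays and the bar is the mean of the 4 array medians. The interferon list lies above 0 on all arrays, from 0.32 on T2 to 1.66 on C2, and the G2/M list below 0 on all arrays, from -1.04 on C2 to -0.17 on T2.

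Reported targets of miR-196a did not shift as a list with either allele. Of 32 measured genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), against 2292 and 2582 of the 21038 genes tested. The median log2 ratio of the list was -0.03, and the camera adjusted p was 0.362. The 4 members with the smallest p were ERG (-0.42 ± 0.11, n = 4; adjusted p = 0.0182), ZMYND11 (-0.52 ± 0.19), the cell cycle inhibitor gene CDKN1B (-0.51 ± 0.24) and HOXB7 (0.24 ± 0.05). HOXC8 had a mean log2 ratio of -0.28 ± 0.20 (adjusted p = 0.0760), with Cy5 well above background on 3 of 4 arrays, and HOXA7 of 0.09 ± 0.14 (adjusted p = 0.389). ANXA1, which encodes a calcium-dependent membrane-binding protein, had 1.61 ± 1.34 (adjusted p = 0.0727), with ratios from -0.04 on T2 to 2.89 on T1. The probes of HOXB8 and HMGA2 did not pass the filter on dim probes, and these genes were not tested.

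On the arrays labelled C, 22 of 21038 genes passed against the empty vector, 12 higher and 10 lower; 12 of the 22 had a current gene symbol, 6 in each direction. DCLK1 had a mean log2 ratio of 2.75 ± 0.08 (SD, n = 2; adjusted p = 0.0389), TFF1 2.24 ± 0.06 with Cy5 saturated on C2, DUSP13A 2.07 ± 0.15 and the potassium channel subunit gene KCNE4 1.92 ± 0.08. KRT8, a keratin gene of luminal epithelium, had 1.49 ± 0.05, also with Cy5 saturated on C2. The long non-coding RNA gene LINC00473, whose Cy3 signal was not well above background, was at least 3.95-fold higher. SPANXA1 (-2.76 ± 0.17), SPANXD (-2.33 ± 0.15), CXCL12 (-2.15 ± 0.04), SCIN (-1.85 ± 0.21), TMT1A (-1.82 ± 0.18) and the retinaldehyde dehydrogenase gene ALDH1A3 (-1.47 ± 0.06) fell. HOXC8 (-0.42 ± 0.07; adjusted p = 0.0767), with Cy5 well above background on 1 of 2 arrays, HOXA7 (0.02 ± 0.02; adjusted p = 0.918) and ANXA1 (1.80 ± 0.99; adjusted p = 0.196) did not pass. At an unadjusted p under 0.05 there were 6747 genes, where chance gives 1052. A dye bias of a probe, with no dye swap, can also give a small p here and on the arrays labelled T. With the labels of C2 and T1 exchanged 549 genes passed, 8 of the 22 among them. TFF1, DUSP13A, KCNE4, KRT8 and SCIN then still passed, LINC00473 (1.22; adjusted p = 0.247), DCLK1 (0.0599), CXCL12 (0.0589), SPANXA1 (0.0649), SPANXD (0.0635), TMT1A (0.0741) and ALDH1A3 (0.0854) did not, and ANXA1 did (2.69; 0.0482). From the group's own 2 arrays alone 2314 genes passed, while without C1 or without C2 only 1 array of the group was left.

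By camera, hypoxia response genes were higher on the arrays labelled C, with a median log2 ratio of 1.03 and an adjusted p of 7.80e-11. None of its 31 genes passed over all genes tested, and 23 rose when adjusted over the list alone. VEGFA, the gene of an angiogenic growth factor, had 1.13 ± 0.16 and NDRG1 2.42 ± 0.62 (n = 2; adjusted p = 0.0507 for each). The type I interferon list had a median of 1.29 (22 of 34 risen and 0 fallen adjusted over the list alone; camera adjusted p = 1.71e-10), the G2/M list -0.65 (0 risen and 19 of 52 fallen; 6.49e-11), the G1/S list -0.33 (0 risen and 9 of 49 fallen; 8.32e-06), the unfolded protein and amino acid stress list 0.28 (10 risen and 1 fallen of 33; 5.85e-05), the p53 list 0.50 (3 risen and 0 fallen of 28; 0.000188), the heat shock list 0.22 (6 risen and 0 fallen of 22; 0.000375), the apoptosis list 0.09 (2 risen and 0 fallen of 31; 0.0256) and the ribosomal protein list 0.34 (28 risen and 1 fallen of 76; 1.01e-08); over all genes tested 0 members of these lists passed. Reported targets had a median of -0.10 (1 risen and 7 fallen of 32 adjusted over the list alone; camera adjusted p = 0.198). With an estimated correlation the adjusted p was 0.847 for the called lists other than G1/S, where it was 0.848. With labels exchanged the p53 and apoptosis calls ended (adjusted p of 0.108 and 0.0744) and the hypoxia median was 0.66, with 0.74 for VEGFA and 1.89 for NDRG1. The medians were then -0.37 for G2/M, 0.20 for p53, 0.12 for heat shock and 0.97 for interferon. The G2/M list had -0.30 on C1 and -1.04 on C2, and the interferon list 0.78 and 1.66. The p53 and apoptosis calls also ended without C2, with medians of 0.19 and 0.17. By camera the apoptosis call ended with no filter on dim probes (adjusted p = 0.0632) and with the replicate block (0.0590). The ribosomal call ended with the scanner software's log ratios (median 0.07; 0.181).

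On the arrays labelled T, 0 of 21038 genes passed the limma test against the empty vector, with a smallest adjusted p of 0.0701 and 5403 genes at an unadjusted p under 0.05. The genes with the smallest p, none of which passed, included several seen with the C labels. Mean log2 ratios were 1.57 ± 0.09 (n = 2) for MSMB, a secreted prostate and mucosal protein gene, 1.44 ± 0.08 for KCNE4, 1.36 ± 0.13 for KRT8, 1.59 ± 0.21 for the kinase gene DYRK4 and 1.13 ± 0.06 for RADIL. TFF1 was saturated in Cy5 on both arrays and was at least 5.20-fold above the empty vector. Ratios below 0 were seen for NRXN3 (-1.51 ± 0.05), SCIN (-1.92 ± 0.15), KLHL28 (-1.04 ± 0.02), the bombesin receptor gene GRPR (-1.10 ± 0.01), SPANXD (-1.37 ± 0.15) and TFPI2 (-1.32 ± 0.17). HOXC8 (-0.13 ± 0.17), HOXA7 (0.16 ± 0.20) and ANXA1 (1.42 ± 2.07) did not pass. With labels exchanged the ratio of MSMB was 0.79 (adjusted p = 0.409), that of RADIL 0.81 and that of ANXA1 0.53. Then 0 genes passed as well, with 5366 at an unadjusted p under 0.05, but from the scanner software's own log ratios 1502 genes passed and from separate channels 3512.

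Estrogen response genes had a median of 0.31 on the arrays labelled T, with 10 risen and 3 fallen of 32 adjusted over the list alone (camera adjusted p = 0.0121, and 0.0949 with labels exchanged). CELSR2 had 1.11 ± 0.14, while CXCL12 (-1.41 ± 0.30) and MYC (-0.95 ± 0.09) had ratios below 0. The type I interferon list had a median of 0.66 (camera adjusted p = 3.87e-05), the unfolded protein and amino acid stress list 0.23 (2 risen and 0 fallen of 33 adjusted over the list alone; 0.00230), the ribosomal protein list 0.39 (33 risen and 0 fallen of 76; 1.48e-11) and the G2/M list -0.30 (0.000101); adjusted over the list alone, 0 interferon and 0 G2/M genes passed. The hypoxia list had a median of 0.05 and was not called (0 risen and 0 fallen of 31 adjusted over the list alone; camera adjusted p = 0.435). With labels exchanged its median was 0.36 (adjusted p = 0.0491, and 0.852 with an estimated correlation). The p53 (0.31), heat shock (0.16) and apoptosis lists (0.15) were then called as well, with adjusted p of 0.0190, 0.0248 and 0.0440, and of 0.852, 0.824 and 0.824 with an estimated correlation. The exchanged medians were 1.05 for interferon, -0.60 for G2/M, 0.33 for the stress list, 0.27 for ribosomal proteins and 0.13 for estrogen response. The interferon list had 1.05 on T1 and 0.32 on T2, the G2/M list -0.43 and -0.17, the stress list 0.35 and 0.12, and the ribosomal list 0.54 and 0.22. The G2/M call ended without T1 (adjusted p = 0.0556) and with median centring, where its median was 0.06. Reported targets had a median of -0.01 (0 risen and 0 fallen of 32 adjusted over the list alone; camera adjusted p = 0.498). With an estimated correlation the adjusted p was 0.856 for each called list.

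Between the alleles, hypoxia response genes were higher on the arrays labelled C than on those labelled T, with a median log2 difference of 0.86 (camera adjusted p = 1.51e-17, and 0.885 with an estimated correlation). Of 31 members 28 had a difference above 0, and 20 rose and 0 fell when adjusted over the list alone, among them PFKFB3, a regulator of glycolysis (1.11, SE 0.14), and ANGPTL4, which encodes an inhibitor of lipoprotein lipase (1.68). With the labels of C2 and T1 exchanged the median difference was 0.28 and the adjusted p 0.0617, and the differences were 0.11 for PFKFB3 and 0.08 for ANGPTL4. From the value table, whose own labels of C2 and T1 are exchanged relative to the scanner outputs, PFKFB3 had -0.11. Type I interferon (0.61; adjusted p = 1.27e-05), p53 target (0.34; 5.88e-05) and heat shock genes (0.26; 0.0136) also had higher medians with the C labels. Median differences (C minus T) of the heat shock genes were 0.017 in Cy5 and -0.099 in Cy3, so their Cy5 levels hardly differed. Medians were lower for the G1/S (-0.32; 3.24e-09), G2/M (-0.38; 1.96e-07), estrogen response (-0.29; 0.000268) and replication-dependent histone lists (-0.13; 0.0308). Between the same-numbered arrays C1 and T1, however, the interferon median was lower on C1 and the G2/M median higher on C1. Adjusted over the list alone, 1 estrogen response gene, IGFBP4, fell and 0 genes of the other 6 lists passed, and with an estimated correlation the adjusted p was 0.885 for each. With labels exchanged camera called 6 lists. The G1/S list kept its sign and its call (-0.29; adjusted p = 9.03e-05), and the G2/M list turned to 0.18 and was called (0.0252). The other called lists had no call as labelled. Medians of the p53, heat shock, histone, interferon and estrogen lists turned sign without a call. Among the 8 lists called as labelled only hypoxia kept its call without each array in turn. The estrogen call ended without C1 (adjusted p = 0.1003), the heat shock call without C1 (0.155) or T1 (0.243) and with median centring (0.401), the interferon call without C2 (0.259) or T2 (0.640), the p53 call without C2 (0.271) or T2 (0.163), the G2/M call without C2 (0.875), the G1/S call without T2 (0.640), and the histone call without any 1 array.

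No single gene passed between the alleles: 0 of 21038 in the limma test, with a smallest adjusted p of 0.612, 1649 genes at an unadjusted p under 0.05 against 1052 by chance, and 58 genes with separate channels. In simulated data with the fitted spread, 74.0% of genes with a 4-fold difference and 2.00% of those with a 2-fold difference were called. Spreads there did not depend on the size of a change, and arrays varied independently, so 0 calls do not exclude 4-fold differences. In the data 127 genes differed by at least 2-fold. The smallest p values above 0 (C minus T) belonged to LINC00473, the small GTPase gene RASD1 (2.58, 95% interval 1.95 to 3.21), COX1 (2.24, 1.48 to 3.01), PFKFB3, GDPD5 (0.79) and the transcription factor gene FOS (1.74, 1.10 to 2.38). The file places the COX1 probe on chromosome 1 at 557430 to 557489 of hg18, so a nuclear copy of the mitochondrial gene cannot be told from that gene. For LINC00473, with Cy3 not well above background on C1 and C2, the Cy5 level differed by 1.16. Much of the difference lay in the Cy3 signal for FOS (-2.12 in Cy3 and -0.38 in Cy5, C minus T) and for COX1 (-1.72 and 0.53, with Cy5 saturated on C2). The smallest p values below 0 belonged to MSMB (-1.59, -1.91 to -1.26), OVOL2 (-1.16), AGR3 (-1.80), the growth factor binding protein gene IGFBP4 (-0.94), HOXC9 (-0.85) and CGNL1, whose second probe had the opposite sign. For the reported targets the differences were -0.30 for HOXC8, -0.14 for HOXA7 and 0.37 for ANXA1, with intervals that include 0. The target list had a median of -0.05 (0 risen and 0 fallen of 32 adjusted over the list alone; camera adjusted p = 0.147). With labels exchanged 0 genes passed, 1732 had an unadjusted p under 0.05, and the difference of each gene above was nearer 0, ANXA1 (2.16) aside. The values were -0.19 for LINC00473, -0.12 for RASD1, 0.52 for COX1, 0.11 for PFKFB3, 0.06 for GDPD5 and 0.39 for FOS. For the genes below 0 before, they were -0.02 for MSMB, -0.06 for OVOL2, -0.12 for AGR3, -0.12 for IGFBP4, 0.10 for HOXC9 and 0.17 for CGNL1. Genes and lists picked for a difference shared by both arrays of a label shrink in this way whatever its cause, so these values do not tell which labels are right.

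Across the 21038 genes, which are not independent replicates, the effects on the arrays labelled C and T had a Pearson correlation of 0.702 and a Spearman correlation of 0.681, and 75.9% of genes had the same sign. Both groups name the same empty-vector numbers, and simulated unchanged groups against shared controls had correlations of at most 0.526 in 100 draws. The covariance was 0.0747 against a simulated 0.00874. Pairs of arrays that name different empty vectors had correlations of 0.461 (C1 with T2) and 0.545 (C2 with T1), with covariances of 0.0529 and 0.0817. The ratios of SCIN were -1.85 with the C labels and -1.92 with the T labels. The controls were too few to split, so part of the excess over the simulated values may come from the shared controls. Dye bias of probes, which no dye swap removed, stays in all these ratios. It may add to these correlations as well, also for pairs that name different empty vectors. With labels exchanged the correlation was 0.695.

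**Figure D4:**
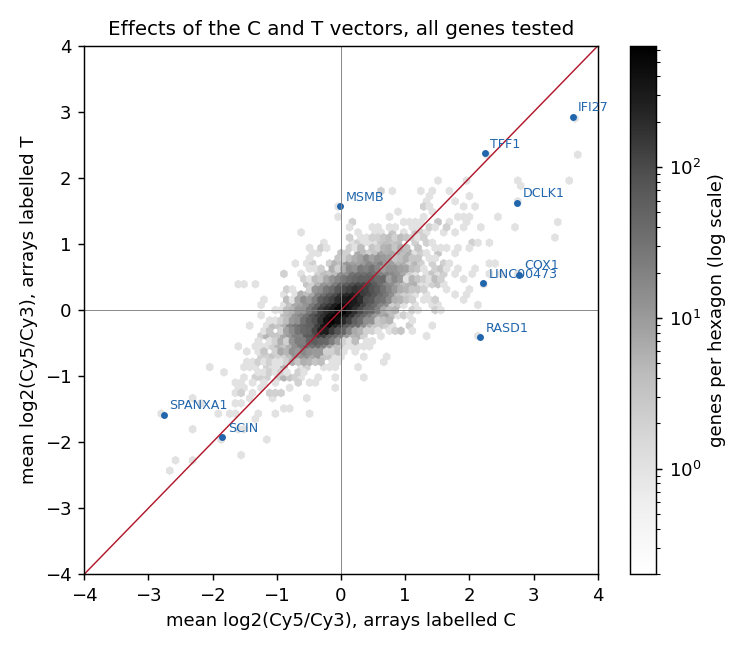
Mean log2(Cy5/Cy3) of the 2 arrays labelled C (horizontal axis) against that of the 2 arrays labelled T (vertical axis) for all genes tested, as hexagons shaded by the number of genes; the line marks equal effects and named genes are dots. SCIN lies near the line, and RASD1 and MSMB away from it; TFF1, saturated in Cy5 on 3 arrays, is a lower bound on the vertical axis.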

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

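All tests of explanations given here were chosen after related values had been seen; the search for outlying arrays and the tests of gene lists between the alleles had been set out before the data were examined.

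The columns of the value table for the arrays labelled C2 and T1 match each other's scanner outputs, so in 1 of these sources 2 labels are exchanged. As the scanner outputs are labelled, arrays naming the same empty vector differed more in Cy3 than other pairs (1.35 times the mean SD of Cy3 differences, 0.239 and 0.255 against 0.113 to 0.264), which argues against an error in the value table. With the scanner labels exchanged, the ratio was 0.477, with SDs of 0.113 and 0.122 for the pairs that then share an empty vector, which is consistent with exchanged scanner outputs. Of the 65 genes with a 2-fold Cy3 difference, 47.7% had one in Cy5 as well. These genes were picked on Cy3, which by itself lowers the share in Cy5. A shift common to neighbouring arrays of the slide, which would pair them under any labels, is therefore not excluded. Both readings rest on the numbers marking separate empty-vector extracts; if each allele had its own extract, the arrays as labelled would pair in this way too, so which label is right stays open.

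Hypoxia response genes differed between the effects of the C and T labels by a median log2 difference of 0.86 (camera adjusted p = 1.51e-17, and 0.885 with an estimated correlation). The empty-vector signals did not carry it, as the list's median Cy3 difference was 0.083. With labels exchanged the difference was 0.28 and no longer past the threshold, but a difference shared by both arrays of a label shrinks in this way whatever its cause, so exchanged labels cannot be told apart from an allele effect by this value. If the scanner outputs carry the exchanged labels, the 0.86 compares the 2 empty-vector numbers, with 1 array of each allele on either side. The list differed by 0.51 between the arrays labelled C1 and C2 and by 0.067 between T1 and T2, while the 4 differences of a C from a T array were 0.61 to 1.22, and with 2 arrays each variation among cultures of 1 allele cannot be told apart from an allele effect. C1 minus T2, the pair with undisputed labels, was 1.22, and an effect of the allele remains open.

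Cytosolic ribosomal protein genes were higher in Cy5 on all 4 arrays, with a median log2 ratio of 0.35. Among 10000 random lists matched on brightness this median lay at percentile 8.68, and the middle 95% of those lists ran from 0.30 to 0.52. A trend of the ratio with brightness that loess left is therefore a candidate explanation; the brightest 2% of genes had a median of 0.32. Dye bias of single probes stays open, since 0 arrays had dyes swapped, and an effect of the vector insert stays open as well.

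Other lists whose effects differed between the C and T labels, by the camera test of the difference itself, were type I interferon response (0.61), p53 target genes (0.34), heat shock response (0.26), replication-dependent histones (-0.13), estrogen response (-0.29), G1/S and S phase (-0.32) and G2/M and mitosis (-0.38), as median log2 differences C minus T. With an estimated correlation the adjusted p was 0.885 for each. For the interferon and G2/M lists the array medians of C1 and T1 ran against the stated direction. With labels exchanged the medians of 6 of the 7 turned sign, G1/S being the exception, and each of the 7 lost its call without some single array. The heat shock list hardly differed in Cy5, with a median difference of 0.017 there and of -0.099 in Cy3.

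The array labelled T2 stood far from the other 3 in 5 of 51 sets of 4 values tested. For independent sets not picked on their values, chance gives about 1 in 20. Most genes among these sets were picked on these same values, and lists share genes, so that rate cannot be applied here. Its log2 ratio was 1.07 for IFI6, -1.33 for PLEKHS1 and 0.30 for HOXA7, and its list median was 0.20 for G1/S and S phase and 0.0347 for DNA damage response and repair.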

How the results depend on the processing

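Exchanged labels, leaving out both disputed arrays, Cy5 alone, averaging by empty-vector number, median centring for gene lists, and everything on either allele were chosen after the data had been seen. Slide and scan blocks were not applicable, and the seed match alternatives were not run. The value table was used under its own column labels. Relative to the scanner outputs, its settings therefore also exchange the labels of C2 and T1. In each setting below the cause of a change was not tested.

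C versus empty vector, with 22 genes, moved by over 1.5 times with nearly every setting. It was 0 with no background correction, with trend and with trend and robust, 549 with labels exchanged, 689 with an offset of 16, 775 with the replicate block, 991 with every probe, 1046 with both exchanged labels and block, 1114 with no filter, 1448 from the scanner's log ratios, 2043 from the value table, 2314 from the group's 2 arrays, 2604 with median centring, 3960 at an adjusted p under 0.10 and 6270 with separate channels; 213 genes were 2-fold in both replicates and 471 on C1 alone. Leaving out T1 or T2 gave the same count as the group's 2 arrays. Without C1 or C2 only 1 array was left for C, which was assumed to vary like those labelled T. T versus empty vector, with 0 genes, gave 109 at 0.10, 572 from the value table, 1502 from the scanner's log ratios, 3512 with separate channels and 4007 with median centring, 85 and 187 by the fold rules, and 0 to 205 (without T2) with 1 array left out. C versus T, with 0 genes, gave 58 with separate channels, and 51 and 447 genes by the fold rules. Median centring raised the share of higher calls to 83.9% for C, against 54.5%. Either allele versus empty vector, with 4874 genes, gave 0 when averaged by empty-vector number and without both disputed arrays. It gave 7614 with separate channels, 7847 at 0.10, 8113 with median centring, 9755 with no filter and 44 by the fold rule. With 1 array left out it gave 0 (without C1 or C2) to 2654. All 27 named genes kept their direction there, but nearly all had been picked for the same sign on all arrays, which fixes this outcome in advance.

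The replicate block left 0 calls for T and for C versus T, and 4262 for either allele, and ended the apoptosis list call for C (adjusted p = 0.0590). Same-numbered arrays deviated together with a correlation of 0.278 over 2 pairs (0.255 with labels exchanged), too few to show that the numbers pair the samples.

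With camera, 0 gene lists were called with an estimated correlation, against 9 for C, 5 for T, 8 for C versus T and 9 for either allele. By fry 0 lists were called in the first 3 and 7 for either allele, of which the apoptosis, stress response and ribosomal lists were among the 9. Median centring gave 15 for T and 16 for either allele, exchanged labels 8 for T, and leaving out 1 array 6 to 12 for T and 5 to 10 for C versus T. The correlation of C and T effects, 0.702, was 0.461 for C1 with T2 and 0.545 for C2 with T1.

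Signs turned in C versus T with exchanged labels for LINC00473 (-0.19), RASD1 (-0.12), HOXC9 (0.10) and CGNL1 (0.17), with or without the block, and for the G2/M (0.18), heat shock (-0.0219), p53 (-0.0924), histone (0.0372), interferon (-0.0056) and estrogen (0.010) list medians; from the value table for CGNL1 (0.41), HOXC9 (0.0553), PFKFB3 (-0.11) and RASD1 (-0.0171); for FOS in Cy5 alone (-0.38); for ANXA1, C versus T, without C1 (-0.32) or T2, with a range of -1.09 to 1.84 over left-out arrays; and for HOXA7, C versus T, without T2 (range -0.285 to 0.0025). ANXA1 turned for T without T1 (range -0.0416 to 2.89), and HOXA7 for C from the value table (-0.0469), the scanner's log ratios (-0.0403) and separate channels (-0.0144). Signals near background limit probes such as HOXC8.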

Other observations

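The tests of seed sites in probes were set out before their results were seen; the comparison of Cy3 signals was made after.

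HOX genes moved in both directions with either allele. Of 20 measured genes 3 rose and 5 fell (4 and 6 adjusted over the list alone), among them HOXB2 (-1.67 ± 0.43, n = 4; adjusted p = 0.0136), HOXC13 (-0.70 ± 0.17), HOXA3 (0.72 ± 0.18) and HOXA10 (0.36 ± 0.10). The list did not shift against other genes (camera adjusted p = 0.362). Estrogen response genes also moved both ways with either allele: beside TFF1, the cadherin gene CELSR2 rose (1.09 ± 0.15; adjusted p = 0.0104), and MYC fell (-0.95 ± 0.15; adjusted p = 0.0114), and the list as a whole did not pass (median 0.095; camera adjusted p = 0.203). By camera, markers of other cell types did not pass as lists either: fibroblast markers had a median of -0.13 (adjusted p = 0.242, but 0.0488 by fry, which does not compare them with other genes), leukocyte markers -0.11 (0.332) and basal and mesenchymal markers 0.019 (0.655). Of the 17 basal and mesenchymal markers, though, 1 rose and 6 fell (2 and 6 adjusted over the list alone).

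FOS and EGR1, transcription factor genes, had lower Cy3 signals on the arrays labelled C than on those labelled T. On the arrays labelled C and T, mean log2 Cy3 signals of EGR1 (chromosome 5, 137832790 to 137832849, hg18) were 11.46 ± 0.07 and 14.02 ± 0.07 (SD, n = 2 each), and those of FOS (chromosome 14, 74817967 to 74818026) 12.08 ± 0.09 and 14.20 ± 0.00. The Cy5 signals were 12.41 ± 0.21 and 13.68 ± 0.12 for EGR1, and 13.40 ± 0.53 and 13.78 ± 0.11 for FOS. They were the only 2 of 32 measured immediate early genes with a 2-fold Cy3 difference, and the list's median difference (C minus T) was -0.25 in Cy3 and -0.19 in Cy5. These genes were chosen after their values were seen, and the difference was not tested. Among 65 genes with a 2-fold Cy3 difference, CD86 had -5.40 in Cy3 and -5.07 in Cy5 (C minus T), so its ratios hardly differed.

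A hypothesis that the vector's microRNA lowers transcripts with a seed site was tested on the probe sequences only, since no transcript reference was used. Probes of 60 bases cover only a small part of a transcript, so sites elsewhere in it were not seen. The 66 genes whose probe holds the 7-base site for the 5p arm had a median log2 ratio 0.017 below the other genes (-0.017) with either allele, at percentile 28.0 of 100 random sites, and the 108 genes with the site for the 3p arm lay at percentile 62.0. Neither was among the lowest 5%. For the C labels alone the median of the 5p site differed by -0.056, where the lowest 5% of random sites began at -0.070. A smaller effect, or one through sites outside the probes, was not tested.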
